A study of Tetrahymena thermophila with 2 samples.

How the data were processed

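Small RNA libraries from 2 immunopurifications of ZZ-tagged Twi12 from Tetrahymena thermophila were re-analysed from the deposited tables, with 1 library in the native group and 1 in the crosslinked group. Per the labels' protocols, gel-purified RNA was ligated to a pre-adenylated 3' adaptor and then to an RNA 5' adaptor, reverse transcribed and amplified by PCR, and no molecular identifiers were described. The same protocol gives an S100 extract for native and an S16 extract for crosslinked purifications.

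The deposited values were counts of reads, per the file headers. For each library the authors deposited a table of all sequences, with the length and the count of reads of each different sequence, and a table of mapped sequences. In the mapped table, the counts were given for the sequence as it matched the reference and for the same sequence followed by C, CC or CCA, with the number of matches in the reference. Every such count above 0 equalled the count of the extended sequence in the table of all sequences. Trimming, the aligner, the reference build and filters were not given in the sources used here. The reads were 15 to 36 nt long, and a read of 36 nt had reached the limit of sequencing, so that its true 3' end was not seen.

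No genome was used here, and reference sequences were therefore reconstructed from the deposited mapped sequences, a step chosen after the files had been seen. For tRNA, every 3' end that the authors' mapped table listed with CC or CCA added in 20 or more reads of both libraries together was a starting point if it fitted the 3' strand of a T arm. It was extended in the 5' direction base by base through overlapping mapped sequences (at least 12 nt of overlap), or, where these ran out, through any sequence with 5 or more reads (at least 16 nt of overlap), following each base that held 10% or more of the reads. A sequence was accepted as complete when it folded into a T arm of 5 pairs, an acceptor stem and an anticodon arm. This gave 51 tRNA sequences with 50 different 3' ends, of which 29 were complete and 22 were 3' parts only. They formed 40 families, 29 with a resolved anticodon that together covered 20 amino acids under the ciliate nuclear code, and the others were named by the encoded 3' end. For rRNA, mapped sequences with 1 match were joined through words of 15 nt into contigs of 60 nt or more, which were named from conserved segments of 5.8S, 17S and 26S rRNA where they held one. Contigs that held none are called other single-match contigs and are counted with rRNA in the sums over all rRNA. Mapped sequences with 13 or more matches in the authors' reference were counted as 5S rRNA on either strand. Antisense reads were counted from 18 nt.

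Each sequence was placed in 1 class by exact match over its whole length, with tRNA before 5S, 5.8S, 17S and 26S rRNA, and then, if unmatched, by a telomere repeat or 5' adaptor word of 12 nt or by a match with 1 substitution, which was not tried for mapped sequences. Mapped sequences in no other class that began with the A box pattern of a tRNA 5' end were kept as a separate class. Shares of tRNA in the text refer to exact matches unless stated otherwise. tRNA positions were counted back from the last A of CCA as position 76. A read of under 36 nt that ended within 3 nt of position 76 was a 3' fragment, a read that began at the first base of a complete tRNA was a 5' fragment, and any other tRNA read under 36 nt was internal. The design, which foresaw a case without a genome, counted as tRNA only the reads that ended in CCA and had a C at position 61, an A at position 58 and a purine at position 57 as far as they reached. This count is given as the tRNA share of the design, and fragment types, families and classes use the reconstructed tRNAs. A read that fitted several families was split equally between them.

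The scripts were tested on simulated data before use. From 200000 simulated reads of 40 tRNAs, all 40 were rebuilt whole with the right anticodon and 0 with a wrong one. These tRNAs were built from largely random sequence without closely related copies, so errors in joining related tRNAs were not tested. The largest error of a family's share was 0.000 percentage points. For this value, reads free of errors were placed against the simulated sequences themselves and not the rebuilt ones, so it tests the placing only. Of the simulated reads with 1 substitution 100.0% were placed, and 0.000% of 20000 random sequences were placed in error. The 100.0% was fixed in advance, because the placing tries every single substitution. Family and position of these reads were not checked. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

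With 1 library per group there was no test across samples and no p-value. Shares have exact Clopper-Pearson 95% confidence intervals, and ratios of shares have exact intervals conditional on the sum of both counts. At depths of 7357054 and 7183780 reads these intervals are narrow, but they cover counting error only, and the limit for a count of 0 rests on 3 counts. Values have 3 significant digits, or 4 where the digit after the point would be 0. The comparisons, the alternatives and the rule for named items were fixed before the data were examined, except for those named as added. The text names the 10 most abundant sequences of each library, the 12 tRNA families with the largest summed shares, the 5 families with the highest and the 5 with the lowest ratio among those with 100 or more reads in each library, and the 5 most abundant sequences outside tRNA and rRNA. The last list was planned for genome loci and was made for sequences instead, and after a first look it was widened to mapped sequences that fitted no class. Shares of named sequences and of 3' fragment starts within 15 to 22 nt, internal reads split by a start at position 55, the strand of the 5S reads and the nearest tRNA of the last list were also added after the results were seen. The alternatives were counting each different sequence once, dropping sequences with under 2 reads, dropping the most abundant sequence, using only mapped sequences, allowing 1 mismatch, other length windows and other rules for reads that fit several families or classes. Planned classes without a reference, which were mitochondrial RNA, small nuclear and nucleolar RNA, signal recognition particle RNA, RNase P RNA, telomerase RNA and protein-coding genes, were not analysed here.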

Results

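Small RNAs that copurified with Twi12, a Piwi protein of the ciliate Tetrahymena thermophila, were sequenced in 2 libraries. Piwi proteins are a branch of the Argonaute family, whose members hold small RNAs as guides. The strain carried Twi12 fused to the ZZ tag, protein A domains that bind IgG, as a cadmium-inducible transgene. No cadmium was added, so that the protein came from leaky expression. In the native library, complexes were purified on IgG-agarose from an S100 extract and RNA labelled as 15 to 34 nt was cloned. In the crosslinked library, the purification followed formaldehyde crosslinking and used an S16 extract, and RNA labelled as 15 to 22 nt was cloned. Each group holds 1 library, so extract, crosslinking and size selection differ together, and no value has a replicate check. The native library held 7357054 reads of 567621 different sequences, and the crosslinked library held 7183780 reads of 499282 different sequences. Shares are given as percentages of reads with exact Clopper-Pearson 95% confidence intervals (CI) where these matter. PCR reads without molecular identifiers are not independent molecules, so intervals and the limits set by a count of 0 cover counting error only. A count of 0 allows a share of up to 4.08e-05% in the native library and 4.18e-05% in the crosslinked library. Every comparison below is between these libraries and not between conditions. Sequences are written in DNA letters, and tRNA families are named by amino acid and anticodon.

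The first question was which read lengths each library held. The libraries were cut from gels at different sizes, so these lengths describe the libraries and do not separate an effect of crosslinking from the size cut. In the crosslinked library, reads of 18 to 22 nt made up 85.3% (CI 85.3–85.3), and the modal length was 20 nt with 21.7%, next to 20.7% at 18 nt and 19.5% at 19 nt. In the native library, reads of 18 to 22 nt made up 20.1% (CI 20.1–20.1) and reads of 25 to 34 nt made up 45.7% (CI 45.7–45.7). Native reads peaked at 27 nt with 7.72% and at 32 nt with 6.15%, and 20.1% were 36 nt long, the limit of the reads, so that their true 3' ends were not seen. The labelled size range held 99.1% of the crosslinked reads and 77.8% of the native reads. Ratios between the libraries were therefore taken only between 15 and 22 nt, a window with 2031775 native and 7116251 crosslinked reads, and shares over other lengths describe each library on its own.

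**Figure D1:**
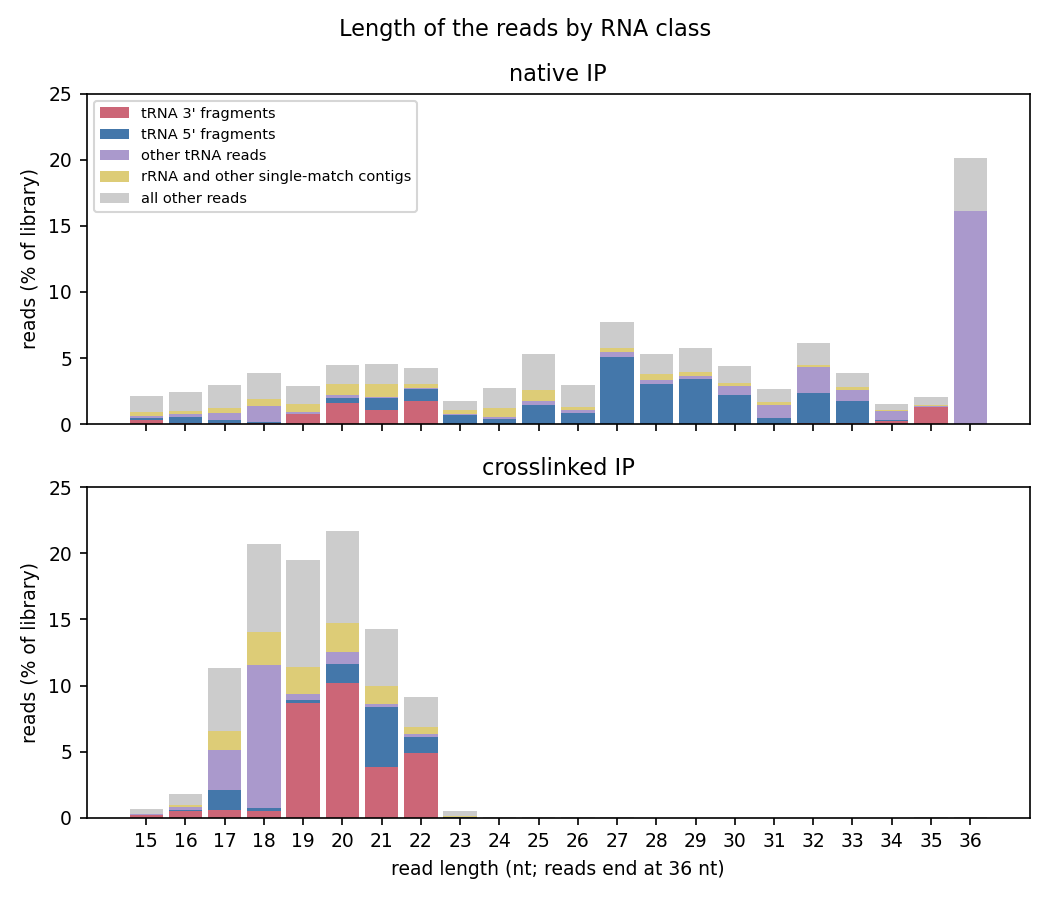
Stacked bars give the share of reads (% of the library, vertical axis) at each read length (nt, horizontal axis) in the native and crosslinked libraries, with tRNA 3' fragments, tRNA 5' fragments, other tRNA reads, rRNA with other single-match contigs, and all other reads in separate colours. The crosslinked reads lie almost wholly between 17 and 22 nt, and the native reads have their highest bar at 36 nt with 20.1%.

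The next question was which RNAs the reads came from. Most reads in both libraries were pieces of transfer RNA, the adaptors that carry amino acids to the ribosome. Exact matches to tRNAs that were reconstructed from the deposited sequences made up 58.03% (CI 57.99–58.1) of the native reads and 54.8% (CI 54.7–54.8) of the crosslinked reads. The 10 most abundant sequences of each library were all tRNA pieces, and they held 33.3% of the native and 24.6% of the crosslinked reads. In the native library, 42.6% of the tRNA reads were 5' fragments, 13.1% were 3' fragments, 16.5% were internal and 27.8% were 36-nt reads whose end was not seen, of which Asp-GTC gave 99.9%. In the crosslinked library, 53.7% were 3' fragments, 16.96% were 5' fragments and 29.3% were internal. A 3' fragment is here a read that ends within 3 nt of position 76, the last base of the mature tRNA, so that pieces that stop just before position 73 count as internal. Reads that started at position 55, like most 3' fragments, made up 14.2% of the native and 79.7% of the crosslinked internal reads. Counted as 3' fragments, they took these to 15.4% of the native and 77.1% of the crosslinked tRNA reads. Limited to reads of 15 to 22 nt, 3' fragments made up 50.1% (CI 50.02–50.2) of the native and 53.8% (CI 53.7–53.8) of the crosslinked tRNA reads.

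The CCA trinucleotide, which is added to tRNA 3' ends after transcription, was a marker of tRNA that needed no reconstruction. Between 15 and 22 nt, CCA was the most common of the 64 possible 3' ends in both libraries, with 9.38% of the native reads (CI 9.34–9.42) and 9.24% of the crosslinked reads (CI 9.22–9.26). The median of the other 3' trinucleotides was 1.04% and 0.720%. Among reads of this size outside tRNA, CCA ended 1.10% and 1.18%. Over all lengths, CCA ended 2.80% of the native reads, where it ranked 9, and 9.21% of the crosslinked reads. Reads that ended in CCA and also fitted the 3' strand of a tRNA T arm, the design's stricter count of tRNA, made up 2.15% (CI 2.14–2.16) of the native and 6.57% (CI 6.55–6.59) of the crosslinked reads over all lengths. Between 15 and 22 nt the order was the other way, with 7.55% (CI 7.52–7.59) of the native and 6.62% (CI 6.60–6.63) of the crosslinked reads. This count misses 5' fragments and 3' fragments without the full CCA, and with the reconstructed tRNAs in its place it was the 58.03% and 54.8% above over all lengths. With each different sequence counted once, the stricter count was 0.621% and 1.57%, and CCA over all lengths was 1.82% and 3.71%.

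Most 3' fragments of 15 to 22 nt shared 1 start. They began in the T loop, at position 55, where tRNAs carry the U of their conserved TΨC motif as pseudouridine. Of the reads with the T arm and complete CCA, 141834 of 158429 (89.5%, CI 89.4–89.7) started at position 55 in the native library and 391485 of 471904 (82.96%, CI 82.9–83.1) in the crosslinked library. The next most common start was position 59, with 1.87% and 5.89%. With each different sequence counted once, position 55 held 41.5% and 42.6%. Of all 3' fragments of 15 to 22 nt, whatever their exact end, 89.6% (CI 89.5–89.7) of the native and 92.5% (CI 92.4–92.5) of the crosslinked reads started at position 55. Over all lengths the native share was 68.4% (CI 68.2–68.5), and the next native starts were position 39 with 10.1% and position 40 with 7.44%, which only reads above 22 nt can hold. This share leaves out the 36-nt reads, which are too long to start at position 55. In the native library 1185981 such tRNA reads had unseen ends, against 382001 3' fragments from position 55. Among them, an Asp-GTC sequence with 247037 reads had already reached position 73. Reads that started at position 55 and reached position 66 or beyond made up 23.7% (CI 23.6–23.8) of all native reads of 15 to 22 nt and 40.4% (CI 40.3–40.4) of the crosslinked ones. The 3' ends varied more. In the native library 27.2% of these reads ended at position 76, with the complete CCA, and 14.6% ended at position 72, the last base of the acceptor stem. In the crosslinked library 12.2% ended at position 76 and 25.04% at position 72. Of all 3' fragments of 15 to 22 nt, 37.1% (CI 36.99–37.3) carried the complete CCA in the native library and 19.9% (CI 19.8–19.9) in the crosslinked library.

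**Figure D2:**
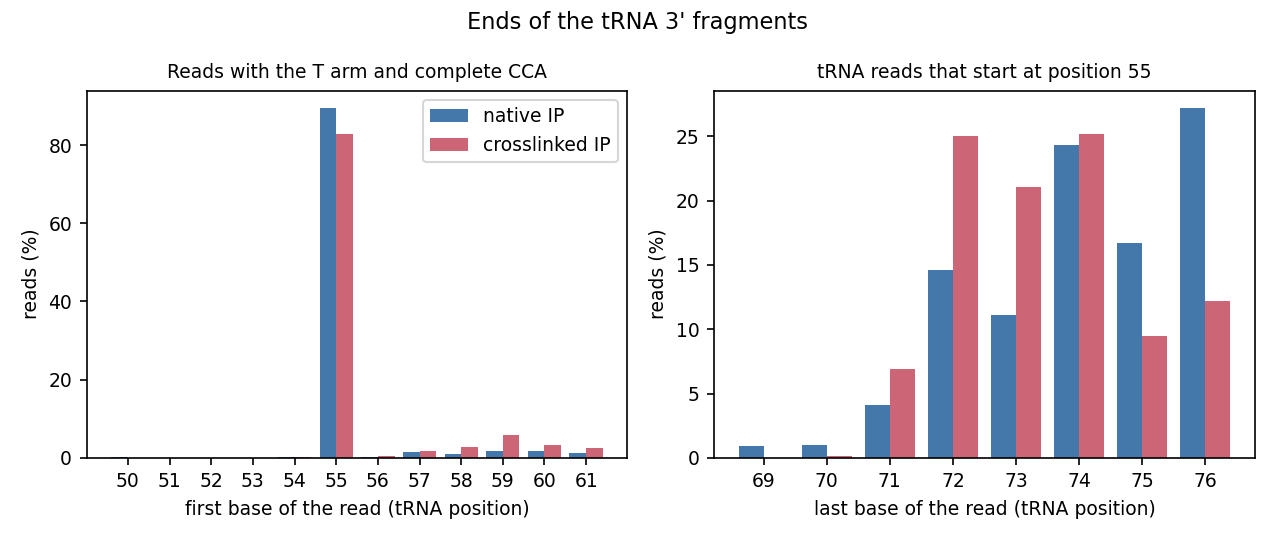
Bars give the share of reads (%, vertical axes) by tRNA position of the first base, among reads with the T arm and complete CCA (left), and of the last base, among tRNA reads that start at position 55 (right), in the native and crosslinked libraries. Starts pile up at position 55 with 89.5% and 82.96%, whereas ends spread over positions 71 to 76.

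The most abundant crosslinked sequences were mainly such 3' pieces. All 10 were 22 nt or shorter, so their shares are given among reads of 15 to 22 nt, the native value last. The first was TCAATTCTCACAGGTGTCGC of Ser-GCT, positions 55 to 74, with 321213 reads (4.51%, CI 4.50–4.53) against 0.586%. Its shorter form TCAATTCTCACAGGTGTC, which stops at position 72, had 2.96% against 0.591%. From Ser-AGA came TCGAATCCTGCAGTTGTCG with 2.77% against 0.413%, TCGAATCCTGCAGTTGTC with 2.48% against 0.468%, TCGAATCCTGCAGTTGTCGC with 2.13% against 0.489%, and TCGAATCCTGCAGCTGAC with 1.40% against 0.210%. Gly-GCC gave TCGATTCCCGGTCGGTGCA with 1.70% against 0.748%, and Val-TAC gave TCAAACCTCGGAGGAATC with 1.43% against 0.713%. A pair of 5' fragments stood among them, CCGAACTTAGCTCAGTTGGAA of Tyr-GTA with 4.09% against 1.97% and GCACCGATGGTTTAGTG of Gly-GCC with 1.33% against 0.711%.

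The most abundant native sequences were longer and came from only the Asp-GTC and Gly-GCC tRNAs. The 36-nt read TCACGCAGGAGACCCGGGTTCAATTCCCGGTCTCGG of Asp-GTC alone had 934180 reads (12.7%, CI 12.7–12.7), and another 36-nt read of this tRNA, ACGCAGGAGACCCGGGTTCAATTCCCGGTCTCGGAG, had 3.36%. The 5' end of Gly-GCC gave GCACCGATGGTTTAGTGGTAGAATAGA with 4.58%, GCACCGATGGTTTAGTGGTAGAATAGAG with 2.57%, GCACCGATGGTTTAGTGGTAGAATAGAGC with 2.36%, GCACCGATGGTTTAGTGGTAGAATAGAGCG with 2.05% and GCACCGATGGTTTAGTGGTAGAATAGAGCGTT with 1.95%. The 5' end of Asp-GTC gave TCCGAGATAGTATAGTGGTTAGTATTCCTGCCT with 1.64% and TCCGAGATAGTATAGTGGTTAGTATTCCT with 0.867%, and its interior gave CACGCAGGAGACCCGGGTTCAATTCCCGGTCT with 1.27%. All 10 were longer than the labelled size range of the crosslinked library, where none had more than 25 reads. Only the 29 complete tRNAs could give 5' fragments, so the order of families holds among these alone, and the 170488 native reads that began with GGTGGATGTAGC and matched no class are not in it. Also outside it are 201374 native reads (2.74%) and 72789 crosslinked reads (1.01%) in the mapped table that fitted no reconstructed tRNA or rRNA but began with the pattern of a tRNA 5' end. Among native 5' fragments of all lengths, Gly-GCC held 67.7%, Asp-GTC 16.1%, Leu-AAG 7.22% and Tyr-GTA 4.53%. Between 15 and 22 nt, Gly-GCC held 38.01% of the native and 26.6% of the crosslinked 5' fragments, Leu-AAG 31.5% and 9.96%, Tyr-GTA 24.4% and 59.9%, and Asp-GTC 2.17% and 2.89%. Of the crosslinked 5' fragments 48.6% were 21 nt long.

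The central comparison asked whether the crosslinked library held the same tRNA families as the native one. In both libraries a few families held most 3' fragments of 15 to 22 nt, and 8 of the 12 largest families were shared. The 4 largest held 68.3% of the native and 70.01% of the crosslinked 3' fragments. Ser-AGA and Ser-GCT had larger shares in the crosslinked library and the glutamate tRNA a smaller one. Ser-AGA held 13.3% (CI 13.2–13.4) of the native and 25.9% (CI 25.8–25.9) of the crosslinked 3' fragments, a ratio of 1.95 (CI 1.93–1.96). Ser-GCT held 9.10% and 23.3%, a ratio of 2.56 (CI 2.54–2.59). Glu-TTC held 35.8% (CI 35.7–35.9) and 8.93% (CI 8.89–8.97), a ratio of 0.249 (CI 0.248–0.251). Val-TAC held 10.1% and 11.9%, a ratio of 1.18 (CI 1.17–1.19), and Gly-GCC held 7.26% and 7.36%, a ratio of 1.01 (CI 1.00–1.03). Across all 40 families the shares of the libraries had a Spearman correlation of 0.90, which describes these libraries and carries no test because families are not independent replicates.

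Among the 34 families with at least 100 reads in each library, 8 were more than 2 times higher in the crosslinked library, 11 were more than 2 times lower and 15 lay between. The highest ratios were 5.27 for Ala-AGC (CI 5.06–5.49; 0.577% native and 3.04% crosslinked), 4.83 for a tRNA with unresolved anticodon whose encoded 3' end is AATCTCACAGTTGCCA (CI 4.69–4.98; 1.04% and 5.04%), 4.25 for Arg-ACG, 3.90 for Val-CAC and 3.64 for Trp-CCA. The lowest were 0.102 for Lys-TTT (CI 0.0978–0.106; 1.87% and 0.190%), 0.238 for the tRNA ending in ATTCCCCGGTGGGTTG, 0.249 for Glu-TTC, 0.324 for Thr-TGT and 0.348 for Asp-GTC. The remaining large families were Cys-GCA with a ratio of 0.496, Gln-TTA with 0.480, Phe-GAA with 0.414 and Arg-TCT with 1.19. Gln-TTA reads UAA, a glutamine codon in the nuclear code of ciliates. The share with the full CCA differed among the 12 largest families, from 1.88% in Cys-GCA to 70.5% in Gln-TTA in the native library and from 1.18% in Gly-GCC to 90.3% in Asp-GTC in the crosslinked library. It was 51.6% native and 6.87% crosslinked in Ser-GCT, and 57.7% native in Asp-GTC.

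The ratios depended on how sequences were weighted and on where a 3' fragment had to end. When each different sequence was counted once, the ratio was 0.887 for Ser-AGA, 0.796 for Ser-GCT, 0.981 for Gly-GCC, 0.880 for Ala-AGC and 0.926 for Arg-TCT, all on the other side of 1. It was 0.809 for Glu-TTC and 0.676 for Lys-TTT, and 1.65 for Arg-ACG, 1.54 for Val-CAC, 1.47 for Trp-CCA and 1.15 for the tRNA ending in AATCTCACAGTTGCCA. For Cys-GCA it was 0.873, for Gln-TTA 0.921, for Phe-GAA 0.823, for Asp-GTC 0.695, for Thr-TGT 0.823 and for the tRNA ending in ATTCCCCGGTGGGTTG 0.563. Leaving out the most abundant sequence of each library took Ser-GCT to 1.05. In the crosslinked library that was a Ser-GCT 3' fragment with 321213 reads, and in the native library a 36-nt Asp-GTC read outside the window. The Ser-GCT sequence stayed in the native library with 11911 reads, so the 1.05 rests on a deletion from the crosslinked side only. A window of 18 to 22 nt took the Ser-GCT ratio to 4.11. With every read that started at position 55 counted as a 3' fragment, Ser-AGA was at 1.99, Ser-GCT at 2.41 and Glu-TTC at 0.198, and Gly-GCC turned to 0.723.

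**Figure D3:**
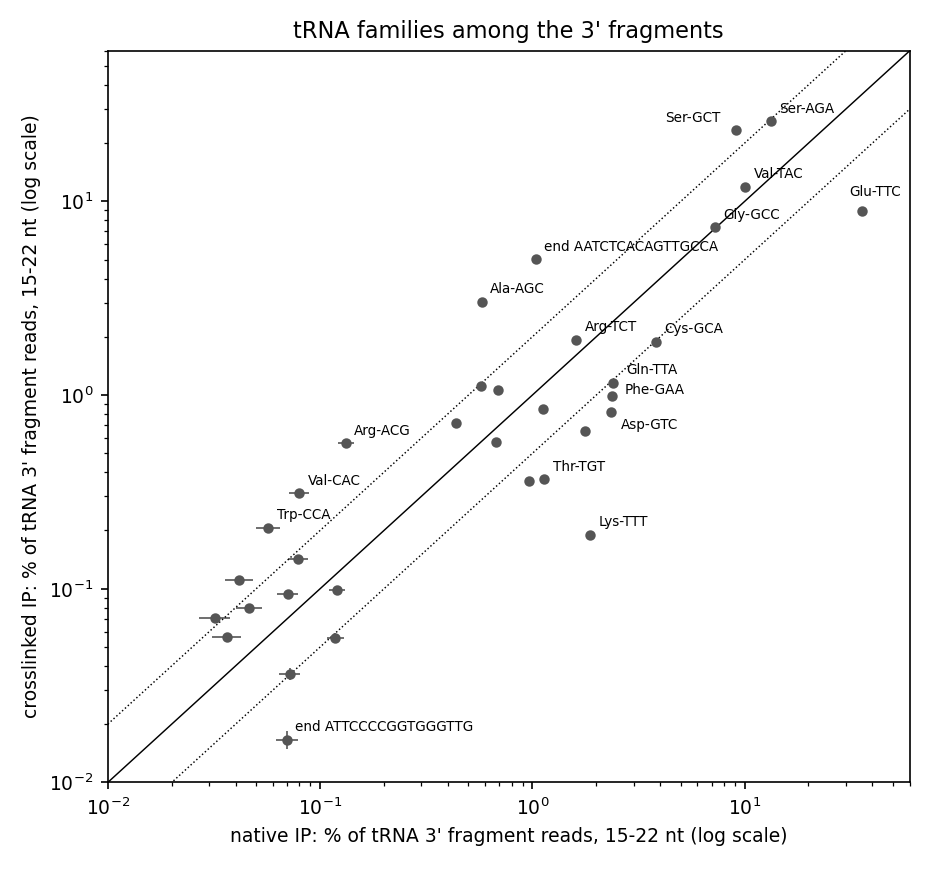
Each point is a tRNA family with at least 100 reads in each library, placed by its share of 3' fragment reads of 15 to 22 nt (%, log scales) in the native library (horizontal) and the crosslinked library (vertical); error bars are exact 95% intervals for counting error, the solid line marks equal shares and the dotted lines mark a 2-fold difference. Ser-AGA and Ser-GCT lie above equality with 25.9% and 23.3% of the crosslinked 3' fragments, and Glu-TTC lies below it with 35.8% of the native ones.

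The same window was then compared by RNA class, with ribosomal RNA as the marker of other abundant cell RNA that a purification can carry. By exact match to the reconstructed tRNAs, transfer RNA had a larger share in the crosslinked library, whereas by the stricter count with CCA and T arm it had a smaller one (7.55% native and 6.62% crosslinked). The named classes of the large rRNAs had smaller shares. Exact tRNA matches made up 41.9% of the native and 55.2% of the crosslinked reads of 15 to 22 nt, a ratio of 1.32 (CI 1.32–1.32). Within tRNA, 3' fragments were 20.99% of the native and 29.7% of the crosslinked reads (ratio 1.41, CI 1.41–1.42), internal pieces were 9.61% and 16.2% (ratio 1.69, CI 1.68–1.69), and 5' fragments were 11.3% and 9.32% (ratio 0.827, CI 0.823–0.831). The internal ratio depended on the cut at position 73, since internal reads that started at position 55 were 4.91% and 12.9% (ratio 2.64, CI 2.62–2.65) and those with another start were 4.70% and 3.26% (ratio 0.693, CI 0.688–0.699). 17S rRNA made up 4.86% and 1.97% (ratio 0.406, CI 0.402–0.409), and 26S rRNA 5.97% and 2.61% (ratio 0.437, CI 0.434–0.441). The other single-match contigs, which were not assigned to an rRNA, made up 3.62% and 3.36% (ratio 0.930, CI 0.922–0.938). Any 26S rRNA among them is missing from the 26S ratio. All rRNA classes with these contigs made up 15.5% and 10.3% (ratio 0.665, CI 0.662–0.668). The small rRNAs went the other way, with 0.182% and 0.966% for 5S rRNA (ratio 5.32, CI 5.15–5.50) and 0.873% and 1.40% for 5.8S rRNA (ratio 1.60, CI 1.58–1.63). The 5S class was set by match number and not by strand. Of its reads in this window, 88.1% of the native and 97.5% of the crosslinked ones shared 12 nt with the 5S contig, 0.0813% and 0.0306% with its opposite strand only, and 11.8% and 2.49% with neither. Sequences that matched none of the classes made up 31.6% of the native and 19.3% of the crosslinked reads. With each different sequence counted once, the tRNA ratio turned to 0.531.

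Within the labelled size range of the native library, short and long reads held different parts of the tRNAs. The long window of 23 to 34 nt leaves out the reads of 35 and 36 nt. At 35 nt, 62.5% of the reads were 3' fragments, which made up 1.27% of the library. At 36 nt, tRNA reads whose ends were not seen made up 16.1% of the library, so the ratios hold for these windows only. Between 15 and 22 nt, 3' fragments made up 20.99% of the reads, against 1.06% between 23 and 34 nt, a ratio of 19.8 (CI 19.6–20.1). Fragments from the 5' end went the other way, with 11.3% against 43.1% (ratio 0.262, CI 0.261–0.263). Exact matches to reconstructed tRNAs made up 41.9% of the short and 57.6% of the long reads (ratio 0.727, CI 0.725–0.728). Exact matches to 26S rRNA were concentrated in the short window, with 5.97% against 0.878% (ratio 6.81, CI 6.72–6.89), whereas 17S rRNA made up 4.86% and 5.04% (ratio 0.965, CI 0.958–0.973). Reads of rRNA with 1 mismatch went the other way, with 1.65% against 3.41% (ratio 0.483, CI 0.478–0.489). At 1 site of 26S rRNA 37437 native reads differed from the mapped sequence, against 32419 exact 26S reads in the long window. Their lengths were not split, so the 26S ratio holds for exact matches to the named contigs only. The other single-match contigs made up 3.62% and 1.29% (ratio 2.80, CI 2.77–2.83). CCA ended 9.38% of the short reads and 0.351% of the long ones, where it ranked 48 of the 64 trinucleotides. The ratio for 3' fragments was 2.01 when each different sequence was counted once.

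The first base of guide RNAs is often fixed in Piwi complexes, and it was tallied over reads of 18 to 22 nt. U was the most common first base, with 48.4% (CI 48.3–48.5) of the native and 61.5% (CI 61.4–61.5) of the crosslinked reads, followed by A with 27.05% and 20.3%. The 3' fragments began with U in 97.6% and 96.95%, and most of them started at the conserved U of position 55. With the internal reads that started there, they made up 31.3% and 44.7% of the reads of this size. Of the U reads, 715796 native and 3767664 crosslinked, 3' fragments gave 382880 and 1960336, and these internal reads gave 70415 and 719449. Reads with A numbered 399920 and 1245301, of which 6210 and 41558 were 3' fragments. Without these tRNA pieces, A outnumbered U in both libraries, so the lead of U came from them. Within them, a choice of U cannot be told apart from this start. Reads of rRNA began most often with A, in 64.8% and 55.4%. The 5' fragments began with G in 65.98% and C in 33.5% of the native reads, and with C in 72.7% and G in 26.4% of the crosslinked reads. Reads that matched no class began most often with A, in 41.1% and 46.02%. Native reads of 23 to 34 nt began with G in 49.96% (CI 49.9–50.01). With each different sequence counted once, U was at 35.9% and 39.3%.

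Reads in the authors' table of mapped sequences made up 70.3% (CI 70.3–70.4) of the native and 68.5% (CI 68.5–68.6) of the crosslinked reads. They were only 4.41% and 4.22% of the different sequences. Of all different sequences, 70.5% and 60.7% were seen once. The next list leaves out tRNA and rRNA matches, exact or with 1 mismatch, mapped tRNA-like 5' ends and 5' adaptor reads. Within this limit, the 5 most abundant native sequences all began with GGTGGATGTAGC and matched no class. They were GGTGGATGTAGCTCAATCGGAAGA with 0.390%, GGTGGATGTAGCTCAA with 0.378%, GGTGGATGTAGCTCAATC with 0.363%, GGTGGATGTAGCTCAAT with 0.282% and GGTGGATGTAGCTCAATCGGAAGAG with 0.213%. The 5 most abundant in the crosslinked library were GCATCGATGGTTTAGTG with 1.01%, which differed by 1 base from the Gly-GCC 5' fragment GCACCGATGGTTTAGTG and was outside the reconstructed tRNAs only by exact match, and ACCAGGATGGTGTAGAGGAA with 0.416%, both in the mapped table, and ACAATGTTCGTTTAGTGTA with 0.361%, ACAAAAAGGGTTAAAAGGC with 0.244% and ACAACGGTTGTATGGTGTA with 0.209%, which matched no class. Among reads of 18 nt or more, those antisense to the reconstructed tRNAs were 0.000293% (CI 0.000151–0.000511) of the reads of both strands in the native library and 0.000258% (CI 0.000118–0.000490) in the crosslinked library. Antisense to the rRNA contigs were 0.0372% (CI 0.0322–0.0427) and 0.0538% (CI 0.0483–0.0599). Mitochondrial RNA, small nuclear and nucleolar RNA, telomerase RNA, other named noncoding RNAs and protein-coding genes were not analysed here, and genome coordinates are not given.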

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

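No test of an explanation was run for the values in this part. The adaptor and telomere values come from reads outside the mapped table and outside the RNA classes that were compared. The length values come from all reads, tRNA included. Each value lay above the limit that a count of 0 allows. Reads that held the 3' end of the 5' adaptor, the last 12 nt of that oligonucleotide, made up 0.217% of the native library and 0.583% of the crosslinked library. Reads that held a telomere repeat word made up 0.0126% of the native library and 0.00315% of the crosslinked library, and Tetrahymena telomeres are built of the repeat TTGGGG. Only words of the TTGGGG strand were searched, so reads of the opposite strand are not in these values. Reads longer than the labelled size range made up 22.2% of the native library and 0.940% of the crosslinked library. In the native library most of these were the 36-nt reads, 20.1% of all reads, of which the Asp-GTC read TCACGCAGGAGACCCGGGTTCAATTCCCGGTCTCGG alone was 12.7%.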

How the results depend on the processing

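No paired analysis was possible because each group holds 1 library and the groups share only replicate number 1. Chosen after the data were seen were the alternatives with only reads of 15 to 34 nt or of 15 to 22 nt, with reconstructed tRNAs and with every read that starts at position 55 as a 3' fragment, and the single value that stands for each comparison here. Values are given as native and then crosslinked, and the cause of a change was not tested unless stated. A value counted as moved when it left its counting interval (for the Spearman correlation, when its 2nd decimal changed), so most of 17 results moved under most alternatives. U stayed above 35% as first base and position 55 stayed above 41% of starts under every alternative run for them.

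With each different sequence counted once, the 18 to 22 nt share was 29.9% and 75.6%, U as first base 35.9% and 39.3%, CCA ends 1.82% and 3.71%, the genome-matched share 4.41% and 4.22%, the tRNA share (CCA with T arm) 0.621% and 1.57%, 3' fragments among tRNA reads 24.99% and 34.9%, and start position 55 41.5% and 42.6%. The Spearman correlation of the families was 0.85, the ratio of 3' fragments between short and long native reads was 2.01, and the crosslinked to native ratio of tRNA reads turned from 1.32 to 0.531. With sequences of 2 or more reads only, the 18 to 22 nt share was 19.5% and 85.8%, U 49.6% and 62.3%, CCA ends 2.87% and 9.45%, the genome-matched share 74.3% and 71.5%, the tRNA share 2.25% and 6.80%, and position 55 90.3% and 83.3%, and the ratios were 21.1 between short and long native reads and 1.24 for tRNA. Without the most abundant sequence, the 18 to 22 nt share was 23.0% and 84.6%, U in the crosslinked library 59.3%, CCA ends 3.21% and 9.64%, the genome-matched share 66.02% and 67.1%, the tRNA share 2.47% and 6.88%, 3' fragments 16.8% and 49.6%, and the tRNA ratio 1.27. The sequence dropped from the native library is 36 nt long, so only the crosslinked side of that ratio lost reads. With mapped sequences only, the 18 to 22 nt share was 18.8% and 86.5%, U 53.5% and 67.5%, CCA ends 3.36% and 11.4%, and the tRNA share 2.80% and 8.47%. With 17 to 21 nt as the size class the share was 18.8% and 87.5%. U over all lengths was 36.8% and 58.5%. Over 15 to 34 nt, native CCA ends were 3.56%, the native tRNA share 2.75% and native 3' fragments 15.6%. Only 3' fragments with complete CCA were 3.77% and 10.7% of tRNA reads, a stricter definition. With every read that starts at position 55 counted as a 3' fragment, a wider definition, they were 15.4% and 77.1%, and the ratio between short and long native reads was 24.5. The tRNA share by exact match to a reconstructed tRNA was 58.03% and 54.8%, and with at most 1 mismatch 66.1% and 64.4%, both wider definitions. All these are over all lengths, and the order of the libraries depended on the window as well. Between 15 and 22 nt the CCA count was 7.55% and 6.62%, and the exact match 41.9% and 55.2%. In the 18 to 22 nt window the tRNA ratio was 1.23.

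Of 126 recomputed ratios of 18 named families, 54 stayed within their counting interval, 66 moved and 6 crossed 1. Of the 6, 1 was Gly-GCC at 0.723 with every read that starts at position 55 counted, and 5 came from counting each sequence once, with Ser-AGA at 0.887, Ser-GCT at 0.796, Gly-GCC at 0.981, Ala-AGC at 0.880 and Arg-TCT at 0.926. The planned tRNA share with 1 mismatch was not run as such, because the CCA count uses no alignment. Depth limits the families with few reads, such as Trp-CCA with 243 native reads, and a single library per group limits every comparison.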

Other observations

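The pairing of the GGTGGATGTAGC reads with tRNA-His and the crosslinked-only test of the last base were chosen after the result was seen, and the adaptor test of the last base was recoded after its first value was seen, without a change of verdict. The most abundant native sequences outside the tRNA and rRNA classes, as limited above, had the sequence of a tRNA 5' strand that pairs with tRNA-His, with a G in front. Reads that began with GGTGGATGTAGC numbered 170488 in the native and 36949 in the crosslinked library, and 0 of them were in the mapped table. Reads with the same start without the first G, GTGGATGTAGC, numbered 991 and 36, of which 936 and 35 were in the mapped table. The first 7 bases of GTGGATGTAGC formed 7 of 7 possible pairs with positions 66 to 72 of the reconstructed His-GTG tRNA. The form with the G held 99.4% (95% CI 99.4–99.5) and 99.9% (CI 99.9–99.9) of both forms. As background, eukaryotic tRNA-His carries a G before its first encoded base that is added after transcription.

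A site in 26S rRNA differed from the mapped sequence by a G-to-A difference in nearly all reads. A was read in 37437 of 37484 native reads (99.9%, CI 99.8–99.9) and in 41 of 41 crosslinked reads (CI 91.4–100). Sequencing or PCR error would have put the base in a small part of the reads, and the lower of both libraries, at 99.9%, argued against it. The same 99.9% was what a base of the strain's rDNA that differs from the mapping reference predicted, and this stays open as a hypothesis. No biological explanation by group was tested.

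Reads of tRNA 3' fragments with another base than A at position 58 had a median of 0.989% over 22 native and 1.06% over 32 crosslinked families. A at this position is commonly methylated in tRNAs, which disturbs reverse transcription. Gene copies outside the reconstructed tRNAs would have given a single substituted base, and the most common base held 56.7% or less of the differing reads in the median family. Mapped sequences were not tried with 1 substitution, so reads from copies in the authors' reference were left out beforehand. The value cannot decide on such copies, and it argued only against copies missing from that reference, in the median family. In some families 1 base was more dominant, with U at 89.2% native and 85.8% crosslinked in Ser-GCT and at 84.3% and 82.8% in Gly-GCC, so copies missing from the reference are not excluded there. The dominance did not follow the number of differing reads. In the native library, the most common base held 59.7% of 2107 such reads in Glu-TTC and 81.1% of 37 in Gly-TCC. Sequencing or PCR error stays open, because the crosslinked median at position 58 was 0.956 times that at position 63, its highest elsewhere. A modified base misread by reverse transcriptase may contribute as well, since 65.6% of crosslinked and 72.7% of native families had a rate at position 58 over 2 times the median of their other positions.

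In 3' fragments, the last base alone differed from the tRNA in 1.11% of the native and 5.74% of the crosslinked reads. The kind of base was counted in another set of reads, which shared the common T-loop start and included mapped sequences. Only differing last bases at positions 73 and 76 were counted in that set. They were mostly U (56.4% and 51.6%) or A (24.7% and 42.9%). The tRNA base at position 76 is A, so every A came from position 73. Substitution error at the end of the read was argued against in the crosslinked library, where the rate was 9.30 times that of the inner positions. In the native library it was 2.50 times, under the limit of 3, so that for both libraries together error and another origin cannot be told apart. A base of the 3' adaptor left on the read would have been C. Of the differing bases counted at positions 73 and 76, C held at most 7.01%, which argued against it at these positions. A base added to the RNA after cutting was not tested.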
